A study of Mus musculus with 2 samples.

How the data were processed

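Total RNA from 2 pools of sorted bone marrow KSL cells was profiled, 1 pool from Nrf2 knockout and 1 from wild-type C57BL/6J mice, with 5 mice in each pool. Per the labels' protocols, RNA was isolated with a Qiagen RNeasy micro kit, amplified and labelled with NuGEN Ovation kits, and hybridised to Affymetrix Mouse Gene ST 1.0 arrays, on which a probe set combines several probes of a transcript. Amplification from few cells can compress or distort differences for single genes. The submitters' processing notes name Partek, with no version and no role. The background correction, normalization and summary of probes are not given in the sources used here.

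The deposited values are log2 intensities, 1 per probe set and array; the log base is not stated and was taken from the values, which reach 13.8 in the wild-type array, more than a natural or decimal log of a scanner's range allows. The sorted values of the 2 arrays differed by at most 0.0866, as happens after quantile normalization between arrays, although no such step is stated. If the arrays were brought to one distribution, a shift of all genes in 1 direction could not be seen. An array has no read depth, and with 1 array per genotype the number of arrays limits the precision.

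Probe sets were named from the platform annotation. Of 28853 probe sets, 21789 had 1 gene symbol, 1621 had several and 5443 had none; only those with 1 symbol entered the comparison. Of these, 21698 matched a gene of the GRCm38.p6 annotation by Entrez ID, which changed 0 symbols. Annotated gene positions were used only for the order of genes around Nfe2l2, and annotated gene length only for matching on gene span. Probe sets of a gene were averaged, giving 19938 genes, of which 999 had more than 1 probe set. Genes whose mean of the 2 arrays reached the median over genes, 6.57 on the log2 scale, passed the level filter. The filter is not a test of detection, and no measure of background was used here.

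Each difference is the log2 knockout value minus the log2 wild-type value, from the deposited values with no further normalization. With no replicates, no test was run and genes were counted by a fixed size, at least 2-fold. The probe-set error of a difference was estimated from genes with exactly 2 probe sets past the filter. A gene list was summarised by the median difference of its members past the filter and by the percentile of this median among 10000 random lists of the same size, drawn from 20 bins of mean level. A median outside the middle 95% of random lists was said to stand apart, which describes these 2 arrays and not the genotypes in general. Of 42 lists, counting the neighbours of Nfe2l2, 40 were scored; the mitochondrially encoded list had 0 measured members and the sex-linked list, with 1 member past the filter, was reported gene by gene. The neighbours were the 30 measured genes on each side of Nfe2l2 in annotation order, with unnamed gene models kept.

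The groups, comparisons, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took Nfe2l2; the 12 highest and 12 lowest differences past the filter, leaving out unnamed gene models, olfactory and vomeronasal receptors, small RNAs and antigen receptor segments; every list member past the filter with a difference of at least 2-fold; up to 4 passing members of each list with the largest absolute difference; Nqo1, Hmox1, Gclc, Gclm, Txnrd1 and Srxn1; and every sex-linked list member. Genes named outside the rule are said to be so.

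The alternatives fixed in advance were median centring, quantile normalization and loess on mean level, no level filter and one at the 75th percentile, the probe set with the highest mean, a 1.5-fold size, unmatched random lists, lists without their largest member, and means in place of medians. Alternatives chosen after seeing the data were random lists matched on level and gene span, counts without myeloid and inflammatory list members or without small RNAs and unnamed models, and lists without members shared with myeloid lists. A second list of neutrophil genes, and a primary granule list drawn from the granulocyte-monocyte priming list, were also written after the first results.

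The procedure was tested on simulated data made from the 9970 genes past the filter, by shuffling their centred differences among genes of similar level. Genes planted at 2-fold higher were called at least 2-fold higher in 54.0% of 50 cases, those at 3-fold in 94.0% and those at 1.5-fold in 8.0%, while 0.43% of unchanged genes were called. Unchanged genes kept the observed scatter by construction, so the 0.43% restates that scatter and is not a measured error rate. Of 100 lists of 25 unshifted genes, 4.0% stood apart, and of lists shifted by 0.2 on the log2 scale 92.0% did. Shuffling removed any shared variation among genes, so the 4.0% follows from the 95% range and does not cover lists whose members vary together. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.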

Results

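KSL cells are the bone marrow cells that carry c-Kit and Sca-1 and lack markers of mature lineages, a population enriched for haematopoietic stem cells and multipotent progenitors. The series compared such cells from young healthy mice with and without the transcription factor NRF2, which is encoded by Nfe2l2 and drives genes of the antioxidant response. Per the labels, the title question was the part NRF2 plays in the survival of haematopoietic stem cells. Marrow of 5 mice aged 8 to 10 weeks was pooled per genotype, KSL cells were sorted, and 1 RNA pool per genotype was profiled on 1 array, so the 2 arrays stood for 10 mice. Each gene therefore had 1 knockout value and 1 wild-type value, no difference had a replicate check, and no p-value was computed. Differences are log2 knockout minus log2 wild type throughout. The number of arrays limited the precision of every value.

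The knockout array held 28853 probe sets with a median log2 intensity of 6.41, and the wild-type array had a median of 6.41 over the same probe sets. Over the 9970 genes past the level filter, the levels on the 2 arrays correlated across genes with r = 0.964, where genes are not independent replicates. The middle 95% of these genes differed by between −0.73 and 0.57, with an SD of 0.33. For comparison, 515 genes measured by exactly 2 probe sets gave an SD of 0.31 for the probe-set error of a single difference, or 0.17 by a robust estimate. That error covers probe behaviour and leaves out the spread between animals, sorts and amplifications.

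The targeted gene Nfe2l2 was not lower on the knockout array beyond the scatter of other genes. Its log2 intensity was 9.07 in the knockout pool and 9.16 in the wild-type pool, a difference of −0.09, or 94.0% of the wild-type level. This placed it at percentile 39.3 of 498 genes of similar level, whose differences had an SD of 0.27. The labels do not say which part of the gene was deleted, and a probe set whose probes lie outside that part would not check the genotype.

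Most genes were at similar levels in both pools, and those that differed were more often lower in the knockout array. Of the 9970 genes past the filter, 41 were at least 2-fold higher and 76 at least 2-fold lower in the knockout array, and 93.4% lay within 1.5-fold. The 12 lowest differences were Tmem267 at −2.88, the neutrophil-secreted Retnlg at −2.66, the chemokine Cxcl10 at −2.40, the siderophore-binding granule protein Lcn2 at −2.10, the cytokine Lif at −2.09, Borcs6 at −2.07, Rida at −2.03, the neutrophil collagenase Mmp8 at −2.00, the inflammatory cytokine Il1b at −1.88, Taf9b at −1.82, the chitinase-like Chil3 at −1.78 and lactoferrin, Ltf, at −1.69. The 12 highest were the inducible heat shock protein Hspa1a at 2.12, the mitochondrial folate enzyme Mthfd2l at 1.96, Hyal3 at 1.88, Hyls1 at 1.56, Fv1 at 1.43, Rnf121 at 1.38, the pseudogene Selenok-ps1 at 1.36, AV039307 at 1.31, the TLR4 co-receptor Ly96 at 1.28, the endosomal RNA sensor Tlr7 at 1.27, Rbm41 at 1.23 and Dear1 at 1.15. In the lower array, 6 of the 12 lowest and 5 of the 12 highest genes were below the filter level of 6.57, where weak signal makes the size of a difference and its rank less sure. Among the 76 lower genes, 18 were members of the neutrophil, monocyte-macrophage, granulocyte-monocyte priming or NF-kB response lists. Among the 41 higher genes, 15 were small non-coding RNA genes, against 2 of the 76 lower genes, and leaving out small RNA genes and unnamed models left 20 higher and 72 lower genes.

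**Figure D1:**
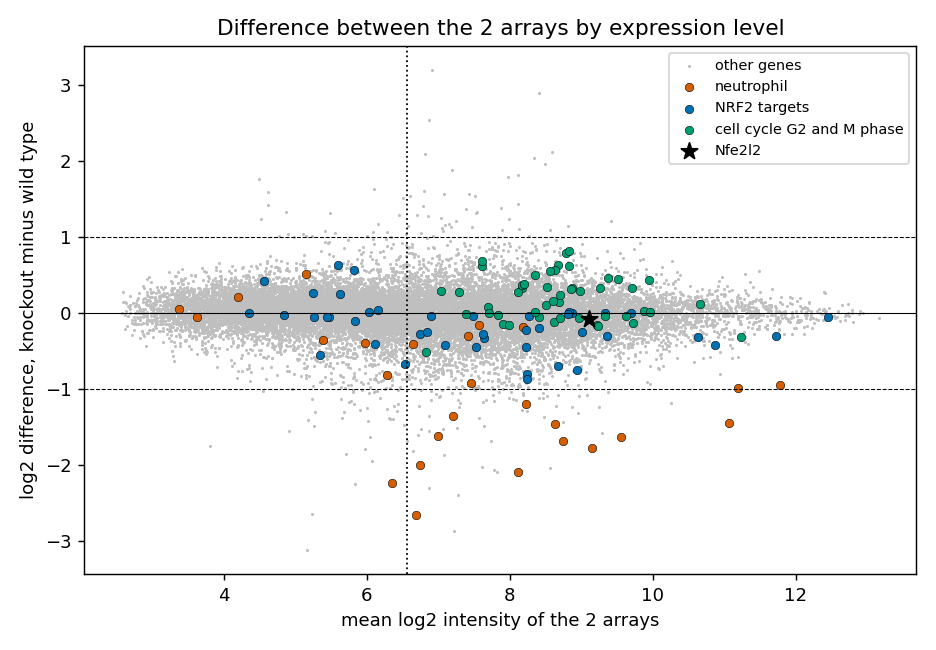
Difference between the 2 arrays (log2 knockout minus log2 wild type, vertical axis) against the mean log2 intensity of the 2 arrays (horizontal axis), with 1 point per gene, the level filter as a dotted vertical line and 2-fold as dashed horizontal lines. Neutrophil genes (orange) lie lowest, with a median of −1.40 past the filter, NRF2 targets (blue) have a median of −0.28, G2 and M phase genes (green) have a median of 0.23, and Nfe2l2 (star) lies at −0.09.

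Of 40 gene lists scored, 10 had a median below and 2 a median above the middle 95% of random lists matched on expression level. If genes were independent, 2 of 40 lists would lie outside that range by chance; members of a list can vary together and some are shared between lists, so chance can give more.

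**Figure D2:**
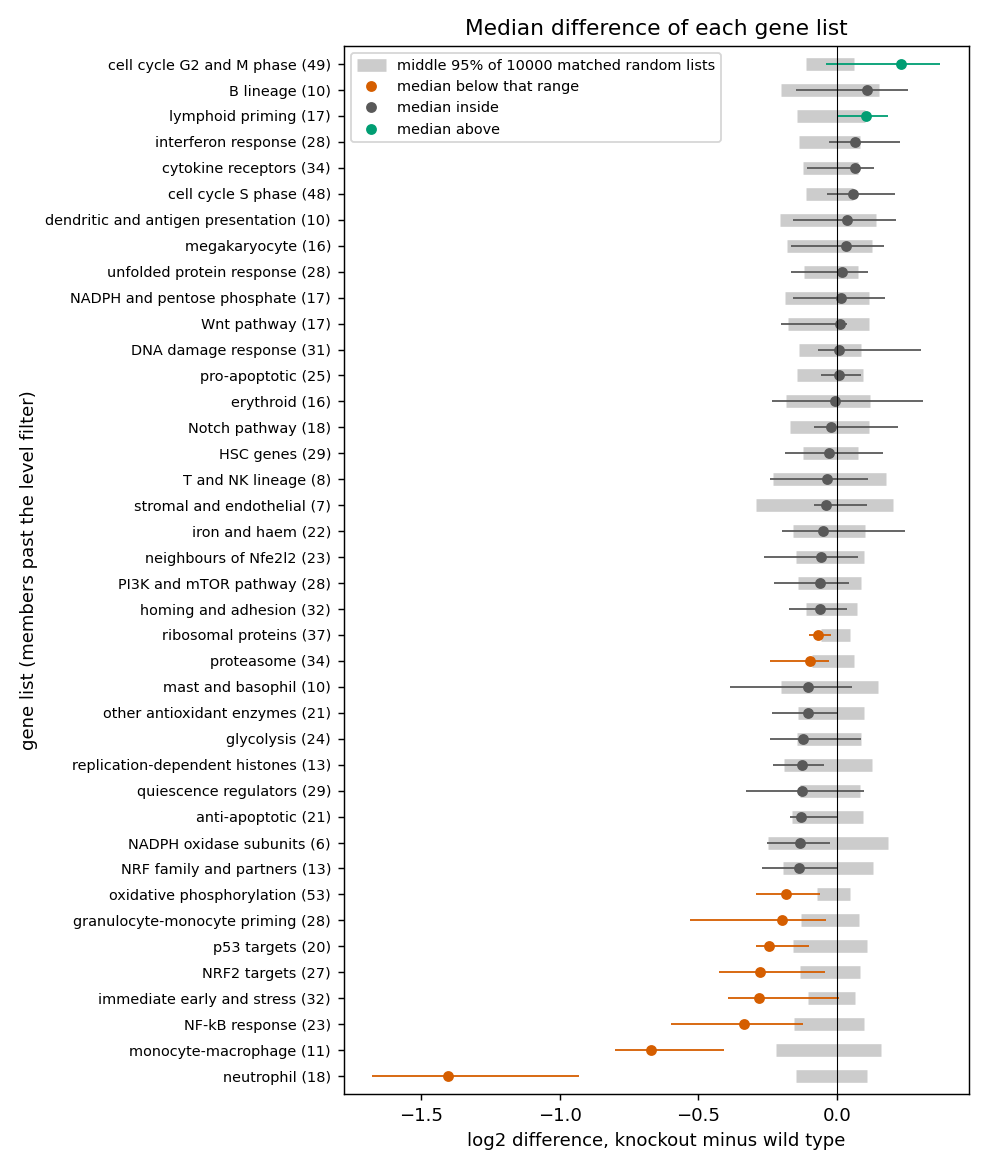
Median log2 difference (knockout minus wild type, horizontal axis) of each scored gene list, with the number of members past the level filter in brackets; points are medians, thin lines run from the 25th to the 75th percentile of the members, and grey bars span the middle 95% of 10000 random lists of the same size and level. The neutrophil list is lowest at −1.40 and the G2 and M phase list highest at 0.23.

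The first comparison asked whether genes that NRF2 is known to drive were lower without it. Of 50 NRF2 target genes listed, 27 passed the filter, and 24 of the 27 were lower in the knockout array. Their median difference was −0.28, below the range of random lists of −0.13 to 0.08. Glutathione reductase, Gsr, was lower by the most, at 7.80 against 8.67, a difference of −0.87. Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis, stood at 7.84 against 8.65, a difference of −0.80. The UDP-glucose dehydrogenase Ugdh differed by −0.75 and the autophagy receptor Sqstm1, also a binding partner of the NRF2 inhibitor KEAP1, by −0.70. The differences were moderate, with 4 of the 27 members at least 1.5-fold lower and 0 at least 2-fold lower. Neutrophil markers were lower in the same array, by a median of −1.40.

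Among classical targets named in advance, thioredoxin reductase Txnrd1 and sulfiredoxin Srxn1 were close to equal in both pools, at −0.01 and −0.04; the sign of Txnrd1 turned with quantile normalization and loess. Gclm, the modifier subunit paired with Gclc, differed by −0.23, near the median of the list. Haem oxygenase Hmox1 stood at 6.19 against 6.86 and the quinone reductase Nqo1 at 5.75 against 5.50; both lay below the level filter of 6.57, where differences are less sure.

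Antioxidant enzymes outside the target list had a median of −0.10 over 21 genes, inside the random range of −0.14 to 0.10, and 15 of the 21 were lower. The secretory-pathway peroxiredoxin Prdx4 differed by −0.67, mitochondrial superoxide dismutase Sod2 by −0.61, and Sesn1 and the glutaredoxin Glrx by −0.31 each. NRF2 relatives and partners had a median of −0.14 over 13 genes, inside the range of −0.19 to 0.13. In that group the ubiquitin ligase subunit Rbx1 differed by −0.70, Nfe2l1 by −0.29 and Nfe2l3 by 0.37. Of the NADPH oxidase subunits, 6 passed the filter with a median of −0.13, inside the range of −0.25 to 0.18. The phagocyte subunit Cybb stood at 8.50 in the knockout and 10.08 in the wild-type array, a difference of −1.59, while Rac2 differed by −0.28, Cyba by −0.19 and Ncf4 by 0.09; the mean of these 6 genes, −0.34, lay below the range of random means.

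The survival question was addressed with genes that block or promote apoptosis. Neither group stood apart from random lists. Anti-apoptotic genes had a median of −0.13 over 21 genes, against a random range of −0.16 to 0.10, and 16 of the 21 were lower. The survival kinase Akt1 differed by −0.64, the NF-kB feedback regulator Tnfaip3 by −0.61, Bcl2l1, which encodes BCL-XL, by −0.54 and the co-chaperone Bag3 by −0.30. Pro-apoptotic genes had a median of 0.01 over 25 genes, against −0.15 to 0.09, with 13 above 0 and 12 below; their mean was −0.02. The BH3-type genes Bnip3 and Pmaip1 differed by −0.99 and −0.49, Bad by 0.45 and the inflammatory caspase Casp1 by 0.38.

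Targets of p53 were lower as a group, with a median of −0.25 over 20 genes against a random range of −0.16 to 0.11, and 17 of the 20 were lower. The stress-induced Gadd45b was 2.03-fold lower, Plk3 differed by −0.50 and Pmaip1, which encodes NOXA, by −0.49. Rrm2b, a ribonucleotide reductase subunit, was higher by 0.50. The p53 list was lower in the array in which neutrophil and NF-kB response genes were lower too, with medians of −1.40 and −0.33.

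The next comparison set genes of the stem cell state against genes of lineage priming. Stem cell genes as a group were level between the genotypes, with a median of −0.03 over 29 genes, inside the range of −0.12 to 0.08. Single members differed: lymphotoxin beta, Ltb, was 2.12-fold lower, the transcription factor Prdm16 differed by −0.80, the adhesion molecule Esam by −0.56 and von Willebrand factor, Vwf, by 0.63. Lymphoid priming genes were slightly higher, with a median of 0.10 and 13 of 17 genes above 0. The upper limit of random lists was also 0.10 when rounded, and the median was inside the range of random lists under 4 alternative settings. The interleukin receptor Il7r and the transcription factor Bcl11a were each higher by 0.25, while Lax1 differed by −0.50 and Gata3 by −0.45. In the same array, neutrophil and monocyte-macrophage markers were lower, by medians of −1.40 and −0.67, and B lineage markers had a median of 0.11.

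Granulocyte-monocyte priming genes were lower, with a median of −0.20 over 28 genes against −0.13 to 0.08, and 22 of the 28 were lower. The granule proteases Elane and Ctsg were 2.18-fold and 2.14-fold lower, the granulocyte-monocyte progenitor gene Ms4a3 differed by −0.92 and the macrophage colony-stimulating factor receptor Csf1r by −0.67. Over the 17 members past the stricter level filter, the median of −0.12 lay inside the random range. Markers of mature neutrophils, which are not KSL cells, were lower in the same array by a median of −1.40. Erythroid genes had a median of −0.01 over 16 genes, against −0.18 to 0.12, with 8 above 0 and 8 below. The red cell enzymes Bpgm and Car1 differed by −0.80 and −0.75, the haem synthesis enzyme Uros by 0.48 and the water channel Aqp1 by 0.45. Megakaryocyte genes had a median of 0.03 over 16 genes, against −0.18 to 0.13, and a mean of −0.03. Platelet factor Pf4 was higher by 0.79, while the platelet glycoprotein Gp5 differed by −0.90, Thbs1 by −0.78 and Gng11 by −0.53.

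By median, the neutrophil and monocyte-macrophage lists were the lowest of the 40 scored lists. All 18 neutrophil genes past the filter were lower in the knockout array, 11 of them at least 2-fold, with a median of −1.40 against a random range of −0.15 to 0.11. Besides Retnlg, Lcn2, Mmp8, Chil3 and Ltf, the antimicrobial peptide Camp differed by −1.64, the chemokine receptor Cxcr2 by −1.63, Pglyrp1 by −1.46, the decoy receptor Il1r2 by −1.36 and Anxa1 by −1.20. S100a8, a subunit of calprotectin, stood at 10.34 in the knockout and 11.79 in the wild-type array. Monocyte-macrophage genes had a median of −0.67 over 11 genes, against −0.22 to 0.16, and 10 of the 11 were lower. Ccl6 differed by −1.52, Ms4a6c was 2.01-fold lower, and Ms4a6b and fibronectin, Fn1, differed by −0.80 each. Ccl6 and Fn1 were below the filter level in the knockout array, at 6.51 and 6.41. The remaining member, Cd68, named outside the rule, was higher by 0.63, at 9.31 against 8.68.

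Markers of other cells that a KSL gate could let through did not stand apart in the main comparison. B lineage genes had a median of 0.11 over 10 genes, against −0.20 to 0.15, with Ly6d higher by 0.67, Vpreb2 by 0.53 and Dtx1 by 0.28, and Cd79b at −0.79. The B lineage list stood apart as higher, with a median of 0.175, without its largest member or with the probe set of highest mean for each gene. T and NK genes had a median of −0.04 over 8, against −0.23 to 0.18, with 4 above 0 and 4 below; Ccl5 and Nkg7, both also in other lists, differed by −0.70 and −0.48, Thy1 by 0.36 and Prf1 by 0.19. Mast cell and basophil genes had a median of −0.10 over 10, against −0.20 to 0.15, with the histamine-forming enzyme Hdc at −0.76 and the eosinophil granule protein Prg2 at 0.52. Dendritic and antigen presentation genes had a median of 0.04 over 10, against −0.21 to 0.14, with H2-Eb1 at −0.45 and Irf7 at 0.27. Stromal and endothelial genes had a median of −0.04 over 7, against −0.29 to 0.20, and a mean of 0.06, with Vwf at 0.63, Emcn at −0.19, Pdgfrb at 0.11 and Col1a2 at 0.10.

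**Figure D3:**
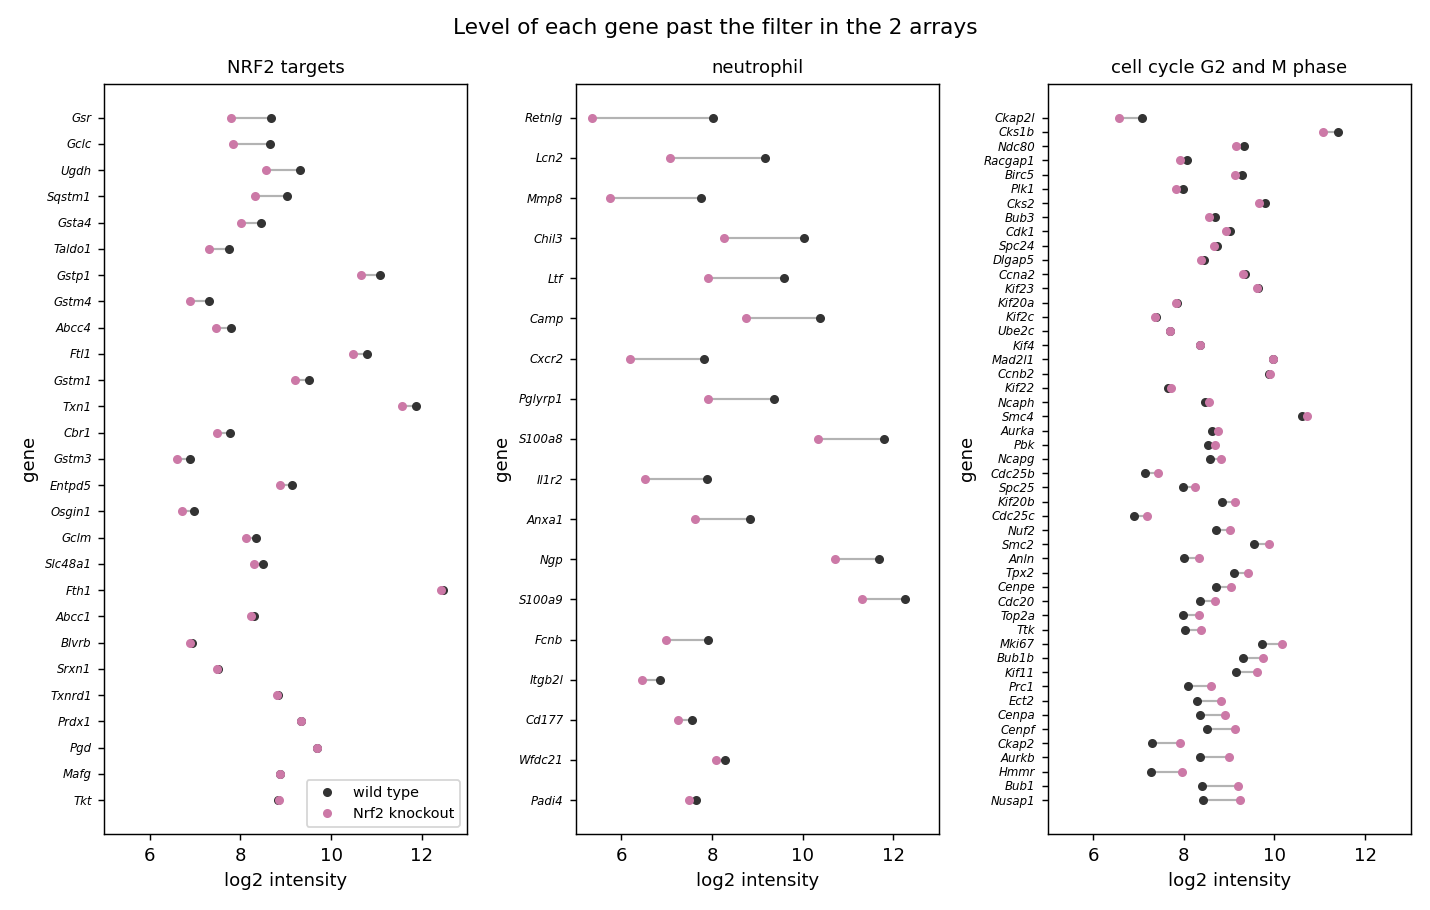
Log2 intensity (horizontal axis) of each gene past the level filter in the NRF2 target, neutrophil and G2 and M phase lists, with 1 point for the wild-type array (dark) and 1 for the Nrf2 knockout array (pink) and a line joining them. All 18 neutrophil genes and 24 of 27 NRF2 targets are lower in the knockout array, and 33 of 49 G2 and M phase genes are higher.

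Mitotic genes as a group were higher in the knockout array, in which neutrophil and monocyte-macrophage markers were lower by medians of −1.40 and −0.67. The G2 and M phase list had a median of 0.23 over 49 genes, against a random range of −0.11 to 0.06, with 33 genes higher and 6 of them at least 1.5-fold higher. The spindle protein Nusap1 was higher by 0.82, the checkpoint kinase Bub1 by 0.79, Hmmr by 0.68 and the kinase Aurkb by 0.63. The rise was not shared by all members, and 15 of the 49 were lower. Named outside the rule, Ccnb2 differed by 0.03, Ccna2 by −0.04, Cdk1 by −0.07 and Plk1 by −0.14. S phase genes had a median of 0.06 over 48 genes, with 31 of 48 higher; this median lay at percentile 97.4 of random lists, inside their middle 95%, and above it under 7 alternative settings. Ung and Tk1 were higher by 0.58 and 0.56, while the thymidylate synthase Tyms differed by −0.58 and the clamp loader Rfc3 by −0.78. Regulators of quiescence had a median of −0.13 over 29 genes, at percentile 3.41 of random lists and inside their middle 95%, with 20 of the 29 lower; the list lay below that range under 2 alternative settings. The cyclin-dependent kinase inhibitor Cdkn2c stood at 6.31, below the filter level, against 7.84, Cdkn2d differed by −0.51, Tsc1 by −0.45 and the retinoblastoma gene Rb1 by 0.41.

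Receptors for cytokines and genes of homing were close to level as groups. Cytokine receptor genes had a median of 0.07 over 34 genes, against −0.12 to 0.08, and a mean that was slightly below 0. Csf2rb, the shared beta chain of myeloid cytokine receptors, was higher by 0.58, Csf1r differed by −0.67, the signalling inhibitor Socs3 by −0.66 and Il18r1 by −0.61. Homing and adhesion genes had a median of −0.06 over 32 genes, against −0.11 to 0.07, with Cxcr2 at −1.63, the integrin chains Itgam at −0.95 and Itga9 at −0.67, and Esam at −0.56. Cxcr2 and Itgam are both expressed by neutrophils, whose markers were lower in this array, and the mean of the homing list, −0.16, lay below the range of random means.

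Inflammatory and immediate early genes were lower. NF-kB response genes had a median of −0.33 over 23 genes, against −0.15 to 0.10, and 21 of the 23 were lower. Cxcl2 was 2.72-fold lower and Ccl5 differed by −0.70. Cxcl10 and Il1b, at −2.40 and −1.88, were below the filter level in the knockout array, so their sizes are less sure. Immediate early and stress genes had a median of −0.28 over 32 genes, against −0.10 to 0.06, with 23 lower and 8 higher. Gadd45b differed by −1.02, Egr2 by −0.95 and Atf3 by −0.93, whereas Hspa1a was 4.33-fold higher. The list's other heat shock genes past the filter, named outside the rule, were higher too: Hsph1 by 0.41, Hsp90aa1 by 0.21, Hspa8 by 0.10 and Dnajb1 by 0.04. The neutrophil and monocyte lists were lower in the same array. Interferon response genes had a median of 0.07 over 28 genes, against −0.14 to 0.08, with Oas1a higher by 0.76, Usp18 higher by 0.62 and Irgm1 at −0.73. Cxcl10 is also a member, and the list stood apart as higher at the 75th percentile filter, with a median of 0.13, and without its largest member, with one of 0.09.

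Sex-linked genes were at similar levels in both pools. Xist, transcribed from the inactive X chromosome, was high in both, at 11.44 in the knockout and 11.14 in the wild-type array. The Y-linked genes were near the bottom of the scale in both, with Eif2s3y at 2.85 and 2.98, Kdm5d at 3.96 and 3.81, and Uty at 3.75 and 3.51. Around Nfe2l2, 23 of the 60 nearest measured genes in the order of GRCm38.p6 passed the filter. Their median was −0.06, inside the range of −0.15 to 0.10. Among these 23 genes, the largest differences were Map3k20 at −0.96, Itprid2 at −0.56, Ube2e3 at −0.51 and Sestd1 at 0.50.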

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

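In this part, the test of the second neutrophil list was set out before its genes' values were seen; all other tests of explanations were chosen after the results were seen. Signal in probe sets that the comparison did not use drew attention: of 1765 probe sets with no gene symbol at or above the filter level, 35 were at least 2-fold higher and 23 at least 2-fold lower in the knockout array, shares of 1.98% and 1.30%, with a largest difference of 3.83. Of 812 probe sets with several symbols, 8 were at least 2-fold higher and 4 lower. Among the 11086 probe sets with 1 symbol, the order was the other way, with 61 higher and 103 lower.

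Neutrophil genes were lower in the knockout array by a median of −1.40, a median that stayed far below random lists matched on level and gene span (−0.18 to 0.09), which argues against those properties as the cause. Carry-over of mature neutrophils into the wild-type pool is a candidate explanation, although the lineage gate of the sort should remove such cells. In a second list of neutrophil genes, none of them in another list, 14 of 16 genes were lower. Its median was −0.35 against a random range of −0.18 to 0.13, a shift far smaller than that of the first list. Other causes of lower neutrophil gene signal would lower this list too, so it does not single out carry-over. The neutrophil probe sets of highest intensity, which does not rank transcripts by amount, were S100a9 (11.30 in the knockout against 12.25), S100a8 (10.34 against 11.79) and Ngp (10.70 against 11.69; S100a9 and Ngp were chosen after their values were seen), and 13 of the 18 members reached the filter level in the knockout array as well; 1 of the 18 is also in another list. The neutrophil median minus that of the granulocyte-monocyte priming list was −1.21, against −0.16 to 0.17 for random pairs. Both medians were known when this comparison was chosen, so it describes a lowering that was not even across the 2 lists and is no separate test. A loss limited to late-primed progenitors stays open. The gap of 0.48 between primary granule and neutrophil medians (SD 0.70 among neutrophil genes) decides nothing. The 5 genes of the primary granule list were picked after their values were seen and include the 3 lowest of the priming list past the filter. Their median of −0.92 is the value of Ms4a3, given above as a progenitor gene. A biological difference in myeloid maturation between the genotypes remains open, as untested.

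NRF2 targets were lower by a median of −0.28; 9 of the 27 genes are also in another list. Random lists matched on level and gene span (−0.16 to 0.07) argue against those properties. A general shift of antioxidant genes stays open: the target median minus that of other antioxidant enzymes was −0.17, just below the random pairs (−0.16 to 0.16). The SD of 0.22 among those enzymes describes single genes and does not measure the precision of this gap. That precision is unknown with 1 array per genotype, and 15 of the 21 enzymes were lower too. Carry-over of neutrophils stays open too: leaving out members of the myeloid lists removed 0 passing targets and left the median at −0.28, and no profile of pure neutrophils was used here. Loss of NRF2 itself remains a candidate biological explanation, set against near-equal Txnrd1 and Srxn1. Prdx1, Pgd, Mafg and Tkt, named outside the rule, were near-equal too, at −0.0009, 0.0013, 0.0015 and 0.0143. In all, 24 of the 27 targets were lower, with Prdx1 counted among them.

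G2 and M phase genes were higher by a median of 0.23, above random lists matched on level and gene span (−0.13 to 0.05). A higher share of sorted cells in the knockout pool would raise stem cell genes alike. Stem cell genes did not rise as a group, with a median of −0.03 inside their random range of −0.12 to 0.08. The G2 and M phase median lay above theirs by 0.26, against −0.13 to 0.13 for random pairs. The SD of 0.36 among stem cell genes, which went both ways, describes single genes and not the precision of this gap. With 1 array per genotype that precision is unknown, so this explanation stays open. More cells in cycle may contribute. The S phase median of 0.0567 lay inside its main random range, at percentile 97.4, but above the range of lists matched on level and gene span, at percentile 98.0. This explanation stays open too. A biological effect of the genotype on mitotic entry or exit was not tested.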

How the results depend on the processing

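The alternatives matched on gene span and those leaving out members of other lists or classes were chosen after the data were seen. No list that stood apart turned to the other side under any alternative run, but 13 lists inside the random range changed sign under at least 1, 7 of them with means, as did 2 named genes: Txnrd1, by quantile normalization and loess, and Flvcr1, by the probe set with the highest mean. The Nfe2l2 difference of −0.09 stayed below 0 under the 4 alternatives that apply to it. This says little, because the gene has 1 probe set and no scaling moved any gene by as much as that difference. The number of lists standing apart lower stayed within 1.5 times of 10 under all 11. Genes at least 2-fold higher and lower numbered 62 and 120 without the level filter and 11 and 29 at the 75th percentile, where more or fewer genes are counted, and 233 and 429 at 1.5-fold; 20 higher and 72 lower genes were left without small RNAs and unnamed models, and 58 lower ones without the neutrophil, monocyte-macrophage, granulocyte-monocyte priming and NF-kB lists. Lymphoid priming no longer stood apart with quantile normalization (0.12), unmatched lists (0.10), means (0.0514) or lists matched on span (0.10). Granulocyte-monocyte priming did not at the 75th percentile filter (−0.12). S phase stood apart with quantile normalization (0.0838), loess (0.084), no filter (0.0567), the 75th percentile filter (0.11), its largest member left out (0.0611), means (0.077) and span matching (0.0567). Quiescence regulators did without the filter (−0.12) and with means (−0.16), and homing genes with means (−0.16). Lists standing apart higher numbered 4 at the 75th percentile filter, 1 with unmatched lists and 5 without the largest members. For these list changes the cause was not tested. Of the other list values, 246 kept their call, 5 gained one (B lineage and interferon response under 2 alternatives each, NADPH oxidase subunits with means) and 9 lost one (ribosomal proteins under 6 alternatives, proteasome under 3). Of the gene values, 705 kept theirs and 3 did not: Ms4a6c, with quantile normalization and loess, and Gadd45b, with loess, no longer reached 2-fold. The scalings moved no gene by more than 0.08. Weak signal limits Nqo1 and Hmox1, below the filter, and the 23 named genes with 1 array below its level.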

Other observations

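No explanation is tested in this part. Oxidative phosphorylation, proteasome and ribosomal protein lists had lower medians in the knockout array, in which neutrophil and monocyte-macrophage markers were lower too, by medians of −1.40 and −0.67. The oxidative phosphorylation list had a median of −0.19 over 53 genes, against a random range of −0.07 to 0.05, with 44 of 53 lower. Its largest differences were those of the complex I subunit genes Ndufb3 at −0.83, Ndufa6 at −0.45, Ndufa10 at −0.40 and Ndufb7 at −0.36, while complex I as a whole was not tested. Proteasome genes had a median of −0.10 over 34 genes, against −0.09 to 0.06, with 27 lower, among them the ATPase subunit Psmc2 at −0.45, Psmb2 at −0.44, Psmb6 at −0.38 and Psmb5 at −0.35. Ribosomal protein genes had a median of −0.07 over 37 genes, against −0.06 to 0.05, with 33 lower and Rplp1 at −0.28. The proteasome list was inside the range of random lists under 3 alternatives and the ribosomal list under 6, matching on gene span, which was chosen after the data were seen, among them for both. Glycolysis genes had a median of −0.12 over 24, inside −0.15 to 0.09, with Ldhb at −0.54 and the pyruvate dehydrogenase kinase Pdk3 at −0.45. NADPH and pentose phosphate genes had a median of 0.01 over 17, inside −0.19 to 0.12, with Mthfd2l higher by 1.96 and the transaldolase Taldo1, also an NRF2 target, at −0.44. Iron and haem genes had a median of −0.05 over 22, inside −0.16 to 0.10, with the haem exporter Flvcr1 at −0.51 as the mean of 2 probe sets but 0.06 by the brighter one, Alas1 at −0.48 and Cpox at 0.43.

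Signalling and genome maintenance lists did not stand apart. Unfolded protein response genes had a median of 0.02 over 28, against −0.12 to 0.07, and a mean of −0.07, with Herpud1 at −0.64 and Ppp1r15b at −0.48. DNA damage response genes had a median of 0.01 over 31, against −0.14 to 0.09, with the repair genes Brca2 higher by 0.74, Ercc1 by 0.65 and Fanca by 0.52, and Xrcc5, which encodes Ku80, at −0.60. Notch pathway genes had a median of −0.02 over 18, against −0.17 to 0.12, with the Notch-responsive repressor Hey1 at 6.32 in the knockout array, below the filter level, against 7.47, and the co-activators Maml1 and Maml2 higher by 0.43 and 0.40. Wnt pathway genes had a median of 0.01 over 17, against −0.18 to 0.12, and a mean of −0.06, with 9 of 17 above 0, the receptor Fzd7 at −0.85, the kinase Gsk3b at −0.37, Apc at 0.30 and Dvl3 at 0.28. PI3K and mTOR pathway genes had a median of −0.06 over 28, against −0.14 to 0.09, with the mTOR subunit Mlst8 higher by 0.83 and Pik3cb at −0.43. Replication-dependent histones had a median of −0.13 over 13, against −0.19 to 0.13, with the linker histone H1f2 2.28-fold lower, H4c4 at −0.43 and H3c4 higher by 0.68.

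Small non-coding RNA genes scattered more widely than other genes. The 121 that passed the filter had an SD of 0.71, against 0.33 over all genes past the filter, and a median of 0.10.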
